A study of Homo sapiens with 12 samples.

How the data were processed

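Total RNA of 3 human breast cancer cell lines was sequenced in 12 libraries. Each line carried a short hairpin RNA against POLE, the catalytic subunit of DNA polymerase epsilon, together with either an empty vector or a POLE cDNA, and each of the 6 groups had 2 libraries. The lines were MDA-MB-231, a basal-like triple-negative line with mutant TP53, CAMA-1, an estrogen receptor positive luminal line with mutant TP53, and MCF-7, an estrogen receptor positive luminal line with wild-type TP53. Per the labels, cells with stable POLE or control constructs were grown in RPMI-10 and RNA was taken with a column kit 5 days after infection with the hairpin. The groups were taken from the sample titles, because a treatment entry in the labels contradicted the titles, and the POLE level of each library matched its title. The labels gave no library with a non-targeting hairpin, no date or batch, and no statement on whether the 2 libraries of a group came from separate cultures, so every p-value measures the spread between these samples and no more. Whether the hairpin also acts on the cDNA was not stated.

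The deposited table held 1 signal value per gene and library, described by the authors as normalized counts. The submitters' processing notes named CASAVA 1.8.4, STAR 2.5.3a, featureCounts from Subread 1.4.6-p3 and DESeq2 1.14.0, and the genome builds mm10 and hg19, without the role or order of any of them. Strandedness, gene annotation and filters were not stated. The values of each library were whole multiples of a single step, and dividing by that step gave whole reads for 100.0% of values at a tolerance of 0.1 read, so the recovered reads were taken as the authors' gene counts before 1 size factor per library. Recovered reads ranged from 25215881 to 35284116 per library and normalized totals from 28396261.02 to 32476747.69. Of 58434 entries, 27 carried a date serial number in place of a gene symbol, the mark of spreadsheet conversion, and were left out. Genes are named by the deposited symbol, the only identifier in the table. No positions are printed, because the annotation at hand (GENCODE 29 on GRCh38) is on another build than the authors'. It served to place neighbouring genes and to find overlapping ones: of 60 genes named for the size of their change, 57 were found in it by symbol and 17 had exons that overlapped another annotated gene, among them NEK9, CCL3, NDRG2, SERPINA9, KRT13, SCIN, KCNMA1 and DIO2, mostly on the other strand. With strandedness unknown, reads of both genes may be joined in those values. Near-identical relatives leave the values of histone genes, CCL3, SAA2, CXCL1, CXCL3, CCDC74A and FAM133A uncertain in the same way.

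Values were analysed as log2(value + 1), a pseudocount of 1, for the 16706 genes with a mean of at least 10 normalized counts over the 12 libraries. A single limma fit with a mean for each of the 6 groups, a trend in the prior variance and 6 residual degrees of freedom gave every contrast, and an adjusted p (Benjamini-Hochberg) under 0.05 was called. All contrasts were coded as vector minus POLE cDNA, so a positive value means a higher level without the cDNA. They were the difference within each line, the mean of the 3 differences, and the difference in MDA-MB-231 minus the mean of those in CAMA-1 and MCF-7. The POLE cDNA arms were also compared between MDA-MB-231 and the mean of the luminal lines, through gene lists alone. Fold changes are powers of 2 of the fitted difference, so the pseudocount makes them understate the change of genes with low values. For genes with 3 or fewer reads over both libraries of an arm, a ratio of reads with a 95% interval, or a lower bound against a floor of 3 reads over the group, is given instead for a difference within a line. For the mean over lines and the difference between lines the fitted value is given, and the genes named by size with so few reads in an arm are named beside it. These intervals and floors cover counting error only, and reads without molecular identifiers are not independent molecules.

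Gene lists, tests, alternatives and the rule for named genes were chosen before the data were examined, except where stated. Named genes were POLE, the other polymerase epsilon subunits, and the largest called changes among genes with a mean of at least 100 normalized counts. Within a line these were 8 in each direction, with that mean in the line and both libraries of one arm above both of the other. For the mean over lines they were 10 in each direction, with that mean over the 12 libraries and the same sign in every line. For the difference between lines they were 6 in each direction, with that mean over the 12 libraries. Names that begin with LOC, LINC, MIR, SNOR or RNU were left out of these. Of each list up to 3 called members with the largest differences were named, or up to 2 with the smallest adjusted p where none was called. Members named beyond this rule were chosen after their values were seen. The lists covered p53 targets, E2F and G1/S genes, replisome genes, mitotic genes, replication-dependent histone genes, DNA damage and fork repair genes, cyclin, CDK and CDK inhibitor genes, interferon-stimulated genes, NF-kappaB and secretory-phenotype genes, immediate early and AP-1 genes, unfolded protein and ATF4 response genes, cholesterol synthesis genes, hypoxia and glycolysis genes, estrogen receptor and luminal genes, basal and mesenchymal genes, lysosome genes, cell death genes, cilium genes, ribosomal protein genes, and genes of fibroblasts and leukocytes. XBP1 is in 2 of the lists. Of 577 listed genes 564 were in the table and 543 were tested. A list of mitochondrially encoded genes had 0 of 13 members in the table and was not analysed. The other 20 lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; adjusted p-values of lists are over the 20 lists of a comparison.

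Alternatives were TMM scaling, size factors computed again within each line, quantile normalization, pseudocounts of 0.5 and 8, no filter and a minimum mean of 50, limma without trend or with robust moderation, edgeR quasi-likelihood and DESeq2 on the recovered reads, a minimum fold of 2, a fit of each line alone, a term for the replicate number, and leaving out each library in turn. Means over pairs of lines, the difference against each luminal line alone, and a minimum mean of 10 within the line were added after the data were seen. So was a measure of low levels that RNA carried over from one line into another would give: the level of genes outside the lists with at least 2000 normalized counts in every library of one line and a mean under 0.2% of that in the other. Low transcription in the receiving line would give such levels too, and the choice of genes bounds them. They were subtracted as carried-over RNA with the level in either arm of MDA-MB-231, in both, or in the same arm as their source. The genes were first chosen by the cDNA arm of the receiving line, which favours a rise, and then by the mean over its 4 libraries. Arm labels were exchanged within lines in 100 drawn relabellings. Correlations of effects between lines are across genes, which are not independent replicates, and carry no p-value.

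On simulated data with 200 of 16706 genes changed, limma called 75%, 82% and 70% of 2-fold changes and 98%, 96% and 97% of 4-fold changes in MDA-MB-231, CAMA-1 and MCF-7. The share of false calls was 13.1%, 9.64% and 13%, above the nominal 5%, and 18, 13 and 18 of the 26, 19 and 25 false calls were of genes with a mean under 10 in that line. For the mean over lines 90% and 98% of changes were called with 5.05% false, and for the difference between lines 53% and 84% with 9.87% false. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.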

Results

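The 12 libraries sampled 6 groups of 2 libraries: MDA-MB-231, CAMA-1 and MCF-7 cells, each with a hairpin against POLE and either an empty vector or a POLE cDNA. The recovered reads per library ranged from 28958813 to 35128325 in MDA-MB-231, from 27255712 to 35284116 in CAMA-1 and from 25215881 to 34222991 in MCF-7. The series title is about CDK2 activity in basal-like breast cancer and targeting POLE. The comparisons therefore ask which transcripts differed between the arms in each line, and whether the basal-like line differed from the luminal ones. Arm and cell population go together in each line, so no such difference, called an effect below, can be assigned to the POLE level alone. In a principal component analysis of the log2 values, the first 2 components separated the lines and held 66.1% and 28% of the variance. The third, with 1.8%, separated the arms of MCF-7, and the fourth, with 1.6%, those of MDA-MB-231.

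POLE was present in every library at a level that followed the construct. In MDA-MB-231 it had 1407 ± 15 normalized counts with the vector and 121011 ± 13820 with the cDNA (mean ± SD, n = 2 libraries each). In CAMA-1 the values were 2391 ± 191 and 168240 ± 13120, and in MCF-7 2910 ± 85.2 and 45336.2 ± 2821. The ratio of cDNA to vector was 86 in MDA-MB-231, 70.4 in CAMA-1 and 15.6 in MCF-7, and the log2 difference of vector minus cDNA was -6.42, -6.14 and -3.96, each with an SE of 0.10. The limma adjusted p was 7.5e-11, 1.22e-10 and 6.76e-09, and both vector libraries of each line lay below both cDNA libraries. The values do not separate endogenous POLE from the cDNA, and without a non-targeting hairpin the strength of the knockdown was not measurable. POLE2, POLE3 and POLE4, the other subunits of the polymerase, were not called in any of the comparisons of arms (in MDA-MB-231 the log2 differences were -0.30, -0.23 and 0.26).

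**Figure D1:**
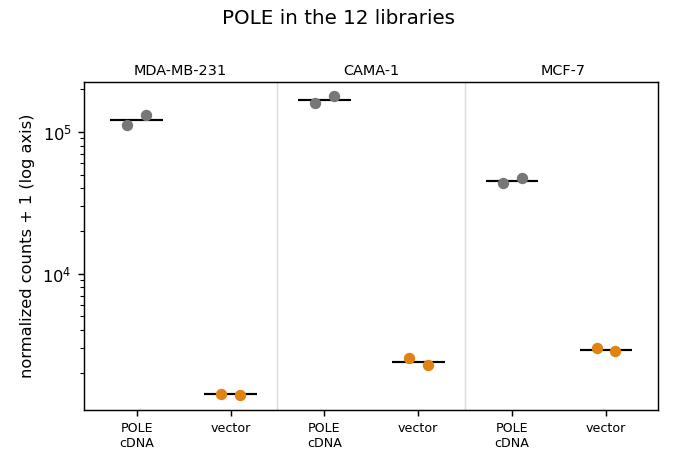
POLE in each of the 12 libraries, as normalized counts plus 1 on a log axis. Points are libraries and bars the mean of 2, with the vector libraries between 1396.24 and 2970.69 normalized counts and the POLE cDNA libraries between 43341.75 and 177517.97.

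In MDA-MB-231 the largest rises without the cDNA, by the rule for named genes, were those of 8 genes. CSF3, a granulocyte growth factor, was 218-fold higher (log2 7.77 ± 0.53, SE, n = 2 libraries per arm, limma adjusted p = 9.43e-06). LCN2, a siderophore-binding protein of innate immunity, was 106-fold higher (6.73 ± 0.42, limma adjusted p = 7.13e-06). The matrix protease MMP3 was 50.9-fold higher, the cytokine IL1B 46.9-fold and NDRG2, of the N-myc downstream-regulated family, 55.9-fold. SERPINA9, a serine protease inhibitor, and the chemokine CCL3 each had 3 reads in the cDNA arm. Their read ratios were 268 (95% counting interval 91.5 to 1300) and 162 (55.1 to 789). The unnamed transcript CTD-3128G10.7 rose by 5.52 on the log2 scale. The largest falls after POLE by the same rule were smaller: RP11-301G19.1 (-2.63 ± 0.43), the oxytocin receptor OXTR (5.17-fold lower) and the helix-loop-helix inhibitor ID1 (4.09-fold lower). CCDC74A (-2.15), NEGR1 (-2.05), ATOH8 (-1.89) and the lipase LIPE (-1.86) followed.

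Of the 32 NF-kappaB and secretory-phenotype genes, 25 rose and 1 fell in MDA-MB-231 (29 and 1 adjusted over the list alone, median 1.64, camera adjusted p = 7.26e-17, adjusted p = 0.117 with an estimated correlation). CXCL5, with 0 reads in the cDNA arm, was at least 53.3-fold higher, and the member that fell was NFKB1 (-0.25). Markers of other cell types moved with this group, though their list was not called (4 and 0 of 6, 4 and 0 adjusted over the list alone, median 0.95, camera adjusted p = 0.0992). CD14 rose by 2.13, CD68 by 1.71, HLA-DRA by 1.32 and COL1A1 by 0.57. PTPRC, the pan-leukocyte gene, stood at 9.36 and 8.38 normalized counts with the cDNA and 2.75 and 2.24 with the vector. Of 34 interferon-stimulated genes 17 rose and 0 fell (19 and 0 adjusted over the list alone, median 0.74, camera adjusted p = 2.75e-07, adjusted p = 0.25 with an estimated correlation), among them the antiviral MX1 (2.10) and RSAD2 (2.69).

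Genes of cell division fell in MDA-MB-231. Of 32 mitotic genes 29 fell and 0 rose (31 and 0 adjusted over the list alone, median -0.87, camera adjusted p = 7.98e-23, adjusted p = 0.126 with an estimated correlation). KIF20A, a kinesin of cytokinesis, was 3.15-fold lower (-1.66 ± 0.10, limma adjusted p = 4.1e-06), the mitotic kinase PLK1 2.7-fold and the spindle protein DLGAP5 2.6-fold. Replisome genes fell in 14 of 33 cases and rose in 0 (14 and 1 adjusted over the list alone, median -0.19, camera adjusted p = 8.15e-06, adjusted p = 0.25 with an estimated correlation). POLA1 (-0.84), a subunit of the priming polymerase, the helicase subunit MCM6 (-0.76) and the ligase LIG1 (-0.69) were among them. Cyclin, CDK and CDK inhibitor genes fell in 7 of 21 cases and rose in 1 (9 and 1 adjusted over the list alone, median -0.37, camera adjusted p = 6.33e-06, adjusted p = 0.126 with an estimated correlation). CKS2 (-1.21) and the inhibitor CDKN2C (-1.13) fell most. The member that rose, CDKN2A, had 3 reads with the vector and 0 with the cDNA, so no fold is given.

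E2F and G1/S genes fell in 8 of 31 cases and rose in 2 in MDA-MB-231 (8 and 2 adjusted over the list alone, median -0.08, camera adjusted p = 0.00672, adjusted p = 0.443 with an estimated correlation). UHRF1 (-0.72), which maintains DNA methylation, the histone chaperone NASP (-0.69) and the folate enzyme DHFR (-0.60) fell. DNA damage and fork repair genes fell in 8 of 33 cases and rose in 0 (8 and 0 adjusted over the list alone, median -0.21, camera adjusted p = 0.00579, adjusted p = 0.52 with an estimated correlation). Among them were WEE1 (-0.90), the kinase that restrains CDK1, FANCD2 (-0.75) and RAD54L (-0.61). Replication-dependent histone genes moved the other way, with 8 of 14 higher and 1 lower (8 and 1 adjusted over the list alone, median 1.25, camera adjusted p = 8.15e-06, adjusted p = 0.237 with an estimated correlation). At the floor of reads in both arms were 5 of the 14, and without them, and with genes at 0 reads in 1 arm set to their bounds, the median was 2.585. HIST2H2BE was 13.3-fold higher (3.73 ± 0.13, limma adjusted p = 7.5e-08), HIST1H2BD 6.79-fold and HIST1H2AC 6.26-fold, and HIST1H1E was the 1 that fell (-1.42).

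Lysosome genes rose in 13 of 28 cases and fell in 1 in MDA-MB-231 (18 and 1 adjusted over the list alone, median 0.37, camera adjusted p = 3.29e-06, adjusted p = 0.271 with an estimated correlation). The sialidase NEU1 (1.34), the lipase LIPA (1.23) and the autophagy receptor SQSTM1 (1.13) rose. Cell death genes rose in 8 of 21 cases and fell in 1 (9 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.000753, adjusted p = 0.117 with an estimated correlation). They joined opposite functions: the survival factor BCL2A1 (read ratio 70.6, 95% counting interval 23.8 to 345) and the death-promoting BIK (2.43) and TNFSF10 (1.72). Hypoxia and glycolysis genes rose in 9 of 25 cases and fell in 1 (10 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.00672, adjusted p = 0.25 with an estimated correlation), with ANGPTL4 (4.33), P4HA2 (1.57) and NDRG1 (1.06) foremost. Immediate early and AP-1 genes rose in 8 of 25 cases and fell in 1 (8 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.025, adjusted p = 0.25 with an estimated correlation), among them IER3 (2.51) and JUND (1.06). Cilium genes fell in 6 of 23 cases and rose in 1 (6 and 1 adjusted over the list alone, median -0.30, camera adjusted p = 0.00973, adjusted p = 0.443 with an estimated correlation), led by TCTN2 (-1.06). Ribosomal protein genes fell in 2 of 38 cases, RPL3 (-0.35) and RPL5 (-0.27), and rose in 0 (0 and 0 adjusted over the list alone, median -0.09, camera adjusted p = 0.015, adjusted p = 0.645 with an estimated correlation).

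The remaining lists were not called in MDA-MB-231, and their members higher and lower are given. The p53 targets (8 and 3 of 35, 8 and 3 adjusted over the list alone, median 0.14, camera adjusted p = 0.0768) included the cell cycle inhibitor CDKN1A (1.87) and TP53INP1 (1.08), in a line with mutant TP53. Basal and mesenchymal genes (7 and 2 of 30, 7 and 2 adjusted over the list alone, median 0.06, camera adjusted p = 0.385) included KRT17 (2.87) and LAMC2 (2.41). Estrogen receptor and luminal genes (6 and 2 of 30, 6 and 2 adjusted over the list alone, median 0.20, camera adjusted p = 0.327) had in several cases levels as low as other genes that are abundant in the luminal lines alone, so no member is named. Unfolded protein and ATF4 response genes (6 and 3 of 29, 7 and 6 adjusted over the list alone, median 0.09, camera adjusted p = 0.725) included ASNS (-1.27) and SLC7A11 (-0.89). Cholesterol synthesis genes (1 and 3 of 23, 1 and 2 adjusted over the list alone, median -0.03, camera adjusted p = 0.385) included SQLE (-0.37).

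In MDA-MB-231 limma called 3913 of 16706 genes, 2358 higher and 1555 lower without the cDNA, and 1231 of them differed at least 2-fold. The higher genes made up 60.3% of the calls, but 49% under quantile normalization. Leaving out a library lowered the count to 2356 (cDNA library 1), 1949 (cDNA 2), 2492 (vector 1) or 1866 (vector 2). Of 73 called named genes 51 were called without each of the 12 libraries, though not NEGR1, ATOH8, LIPE, RSAD2, CDKN2A, CD68, HLA-DRA, POLA1, FANCD2, RPL3 and RPL5. Without vector library 2 camera no longer called the E2F list (adjusted p = 0.124) and the DNA damage list (adjusted p = 0.0526). The ribosomal list was lost without cDNA library 1 (camera adjusted p = 0.203) or vector library 1 (adjusted p = 0.523).

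In CAMA-1 few genes changed besides POLE, and those were mostly higher without the cDNA. GPER1, a membrane estrogen receptor, was 2.39-fold higher (log2 1.26 ± 0.20, SE, n = 2 libraries per arm, limma adjusted p = 0.0457) and TNFAIP3, an inhibitor of NF-kappaB signalling, 2.09-fold (1.06 ± 0.16, limma adjusted p = 0.0406). The kinesin KIF3C rose by 1.12, the triglyceride enzyme DGAT2 by 1.00, TACC1 by 0.91 and the ion exchanger SLC9A7 by 0.87. The transcription factor IRF1 rose by 0.87 and the sterol acyltransferase SOAT1 by 0.64. The chemokine CCL20 was 5.69-fold higher (2.51 ± 0.36, limma adjusted p = 0.0331), and SAMD9L, with 1 read in the cDNA arm, had a read ratio of 19.5 (95% counting interval 3.12 to 808). Besides POLE the 1 gene that fell, RP11-214O1.2 (-1.78, limma adjusted p = 0.0487), was chosen after its values were seen.

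Of 32 NF-kappaB and secretory-phenotype genes 2 rose and 0 fell in CAMA-1 (17 and 0 adjusted over the list alone, median 0.77, camera adjusted p = 6.35e-19, adjusted p = 0.174 with an estimated correlation). Basal and mesenchymal genes had 0 of 30 called (5 and 0 adjusted over the list alone, median 0.52, camera adjusted p = 5.79e-06, adjusted p = 0.188 with an estimated correlation), with NT5E at 1.16 (limma adjusted p = 0.0975) and FN1 at 0.72. Low levels of other genes moved with both lists. The 44 genes outside the lists that were abundant in MDA-MB-231 and near silent in CAMA-1 stood at a median of 0.0625% and 0.055% of their MDA-MB-231 cDNA level in the CAMA-1 cDNA libraries, and at 0.129% and 0.0853% in the vector libraries. Whether these low levels were RNA carried over from MDA-MB-231 or transcription in CAMA-1 itself was not told apart. What subtracting them as carried-over RNA did depended on the MDA-MB-231 arm taken as their source. With the cDNA arm, both arms, the vector arm or the same arm as source, the basal median was 0, 0.018, 0.288 or 0.376 (camera adjusted p = 0.172, 0.0955, 0.00169 and 0.00421). The NF-kappaB median was 0.765, 0.742, 0.502 or 0.405 (camera adjusted p = 2.25e-15, 1.64e-17, 8.97e-17 and 5.16e-05).

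Other called lists of CAMA-1 shifted little. E2F and G1/S genes had 0 of 31 called (0 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 8.7e-08, adjusted p = 0.222 with an estimated correlation), with CDC6 at 0.28. Replisome genes had 0 of 33 called (3 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 1.36e-07, adjusted p = 0.222 with an estimated correlation), with POLA2 at 0.41 and FEN1 at 0.33. Interferon-stimulated genes had 1 of 34 higher (4 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 7.05e-07, adjusted p = 0.259 with an estimated correlation). The p53 targets, also in a TP53-mutant line, had 0 of 35 called (2 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 0.000319, adjusted p = 0.222 with an estimated correlation), with FAS at 1.29 (limma adjusted p = 0.0573). DNA damage and fork repair genes had 0 of 33 called (0 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.000909, adjusted p = 0.686 with an estimated correlation). Estrogen receptor and luminal genes had 0 of 30 called (0 and 0 adjusted over the list alone, median -0.18, camera adjusted p = 1.54e-05, adjusted p = 0.211 with an estimated correlation), with GATA3 at -0.26 and AGR2 at -0.49. Histone genes had 0 of 14 called (0 and 0 adjusted over the list alone, median -0.17, camera adjusted p = 0.000291, adjusted p = 0.259 with an estimated correlation), with HIST1H1E at -1.02.

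Lists not called in CAMA-1 follow with their members higher and lower. They were mitotic genes (0 and 0 of 32, 0 and 0 adjusted over the list alone, median -0.07, camera adjusted p = 0.251), cyclin, CDK and CDK inhibitor genes (0 and 0 of 21, 1 and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.633) and immediate early and AP-1 genes (0 and 0 of 25, 2 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.372). Stress and metabolic lists were unfolded protein genes (0 and 0 of 29, 0 and 0 adjusted over the list alone, median -0.04, camera adjusted p = 0.235), cholesterol synthesis genes (0 and 0 of 23, 0 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.109) and hypoxia genes (0 and 0 of 25, 0 and 0 adjusted over the list alone, median -0.02, camera adjusted p = 0.933). Lysosome genes (0 and 0 of 28, 0 and 0 adjusted over the list alone, median 0.03, camera adjusted p = 0.642), cell death genes (0 and 0 of 21, 0 and 0 adjusted over the list alone, median 0.001, camera adjusted p = 0.783) and cilium genes (0 and 0 of 23, 0 and 0 adjusted over the list alone, median -0.004, camera adjusted p = 0.926) were not called either. The last were ribosomal protein genes (0 and 0 of 38, 0 and 0 adjusted over the list alone, median 0.02, camera adjusted p = 0.91) and fibroblast and leukocyte genes (0 and 0 of 6, 0 and 0 adjusted over the list alone, median 0.23, camera adjusted p = 0.673). The sign of the test was opposite to the median for the hypoxia and ribosomal lists.

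In all, limma called 29 genes in CAMA-1, 27 higher and 2 lower, with 1238 at an unadjusted p under 0.05. On the recovered reads edgeR called 50 and DESeq2 137, of which 18 and 21 were among the 29. A fit of the CAMA-1 libraries alone called 0, quantile normalization gave 15 and no filter on low values 14, while a pseudocount of 8 gave 50, a minimum mean of 50 gave 47 and moderation without trend 45. The count was 6 without any 1 of the 4 MDA-MB-231 libraries, whose spread enters the shared fit. It was 8 without cDNA library 2, 7 without vector library 1 and 8 without vector library 2 of CAMA-1, and 89 and 88 without vector libraries 1 and 2 of MCF-7. Of 11 called named genes only POLE was called without each of the 12 libraries.

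In MCF-7 the largest rises without the cDNA, by the rule for named genes, were those of 8 genes with differing functions. LAMB1, a laminin chain, was 68.9-fold higher (log2 6.11 ± 0.32, SE, n = 2 libraries per arm, limma adjusted p = 1.33e-06), and DLC1, a Rho GTPase-activating protein, 40-fold (5.32 ± 0.15, limma adjusted p = 1.15e-08). The collagen COL12A1 was 36.2-fold higher, the actin-severing protein SCIN 46.2-fold, the semaphorin SEMA3D 38.1-fold, the keratin KRT13 29.3-fold and FAM133A 62.2-fold. The mitotic kinase gene NEK9 had 23.16 and 21.56 normalized counts with the cDNA and 703.28 and 766.89 with the vector (4.98 ± 0.09, limma adjusted p = 2.21e-10), while every library of the other lines had at least 2322.75. Among the largest falls, the complement component C3 was 35.4-fold lower (-5.15 ± 0.27, limma adjusted p = 1.26e-06), the calprotectin subunit S100A8 35.8-fold and LCN2 24.8-fold. CHI3L2 (-5.31), the neural transcription factor ASCL1 (-4.67), the protease ADAMTS9 (-4.30), DSCR8 (-4.21) and the growth factor GDNF (-4.10) fell as well.

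The p53 targets rose in MCF-7, the line with wild-type TP53: 24 of 35 were higher and 1 lower (30 and 1 adjusted over the list alone, median 0.66, camera adjusted p = 5.62e-11, adjusted p = 0.13 with an estimated correlation). EDA2R was 3.99-fold higher (2.00 ± 0.33, limma adjusted p = 0.00182) and the death receptor FAS 3-fold. Chosen after their values were seen, MDM2, the ligase that degrades p53, rose by 1.08 and CDKN1A by 0.70. The member that fell was PLK2 (-0.72). Histone genes fell in 11 of 14 cases and rose in 0 (12 and 0 adjusted over the list alone, median -0.92, camera adjusted p = 2.66e-07, adjusted p = 0.218 with an estimated correlation), including HIST1H1E (-1.91).

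In MCF-7 basal and mesenchymal genes rose in 10 of 30 cases and fell in 1 (10 and 1 adjusted over the list alone, median 0.58, camera adjusted p = 4.86e-06, adjusted p = 0.168 with an estimated correlation). The caveolin CAV1 was 21.4-fold higher, ANXA1 14.6-fold and NT5E 12.3-fold. NF-kappaB and secretory-phenotype genes fell in 11 of 32 cases and rose in 2 (12 and 4 adjusted over the list alone, median -0.41, camera adjusted p = 0.0029, adjusted p = 0.7 with an estimated correlation). With low levels subtracted as RNA carried over from MDA-MB-231, at a source level from its cDNA arm, both arms, its vector arm or the same arm, the NF-kappaB median was -0.428, -0.561, -0.435 or -1.048. The basal median was 0.474, 0.456, 0.557 or 0.538. The 42 genes that measured them stood at 0.0871% and 0.022% of their MDA-MB-231 level in the MCF-7 cDNA libraries and at 0.08% and 0.108% in the vector libraries. TNF had a read ratio of 33.5 toward the cDNA arm (95% counting interval 8.92 to 282). The adhesion molecule ICAM1 was 9.23-fold lower (-3.21 ± 0.23), with BIRC3 at -3.16 and TNFAIP3 at -2.81.

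Immediate early and AP-1 genes rose in 10 of 25 cases and fell in 3 in MCF-7 (10 and 4 adjusted over the list alone, median 0.39, camera adjusted p = 0.014, adjusted p = 0.275 with an estimated correlation), with FOS 10.5-fold higher and IER3 at -1.84. DNA damage and fork repair genes rose in 6 of 33 cases and fell in 1 (7 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 0.0328, adjusted p = 0.822 with an estimated correlation), among them NBN (2.03-fold higher), a sensor of double-strand breaks. Lists not called follow with members higher and lower. Those of the cell cycle were E2F and G1/S genes (7 and 0 of 31, 8 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 0.0894), replisome genes (5 and 0 of 33, 4 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.0894), mitotic genes (3 and 2 of 32, 1 and 2 adjusted over the list alone, median -0.07, camera adjusted p = 0.857) and cyclin, CDK and CDK inhibitor genes (6 and 4 of 21, 7 and 5 adjusted over the list alone, median 0.01, camera adjusted p = 0.717). CDKN2B (2.01) and CDKN2D (-1.45), both CDK inhibitors, moved in opposite directions. Interferon-stimulated genes (4 and 4 of 34, 5 and 4 adjusted over the list alone, median 0.19, camera adjusted p = 0.484) included SAMD9 (3.58) and CMPK2 (2.65). Unfolded protein genes (3 and 7 of 29, 3 and 11 adjusted over the list alone, median -0.08, camera adjusted p = 0.0894) included XBP1 (-1.70), and estrogen receptor and luminal genes (9 and 5 of 30, 10 and 8 adjusted over the list alone, median 0.28, camera adjusted p = 0.329) the estrogen-regulated PDZK1 (2.89).

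Lysosome genes of MCF-7 (0 and 3 of 28, 0 and 3 adjusted over the list alone, median -0.09, camera adjusted p = 0.232) included the protease CTSZ (-2.21), and cell death genes (2 and 0 of 21, 2 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.673) the activator HRK (2.53). Cholesterol synthesis genes (3 and 3 of 23, 3 and 4 adjusted over the list alone, median -0.11, camera adjusted p = 0.488) included SQLE (0.71), and hypoxia and glycolysis genes (1 and 5 of 25, 1 and 5 adjusted over the list alone, median -0.17, camera adjusted p = 0.232) included HK2 (-0.80), the first enzyme of glycolysis. Cilium genes (3 and 3 of 23, 3 and 3 adjusted over the list alone, median -0.08, camera adjusted p = 0.698), ribosomal protein genes (3 and 0 of 38, 3 and 0 adjusted over the list alone, median 0.01, camera adjusted p = 0.306) and fibroblast and leukocyte genes (0 and 1 of 6, 0 and 1 adjusted over the list alone, median -0.51, camera adjusted p = 0.306) were not called.

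In MCF-7 limma called 3219 genes, 1728 higher and 1491 lower, and 1212 differed at least 2-fold. A fit of the MCF-7 libraries alone called 105, and without cDNA library 1 of MCF-7 the joint fit called 2063. Of 73 called named genes 47 were called without each of the 12 libraries. Without a library camera no longer called the DNA damage list (cDNA 1, adjusted p = 0.226, and vector 2, adjusted p = 0.832), the NF-kappaB list (cDNA 1, adjusted p = 0.0577) and the AP-1 list (vector 1, adjusted p = 0.0753). Spread beyond counting error was widest between the vector libraries of MCF-7, with a chi-square of 53.99 per degree of freedom against 6.33 to 25.01 in the other 5 groups. The residual SD was 0.3404 in MCF-7, 0.2921 in MDA-MB-231 and 0.2881 in CAMA-1, while the joint fit took 1 spread per gene over all lines. The MCF-7 calls thus borrow the tighter spread of the other lines, and their p-values may be too small. The simulation, with 1 dispersion per gene for all groups, could not show this.

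**Figure D2:**
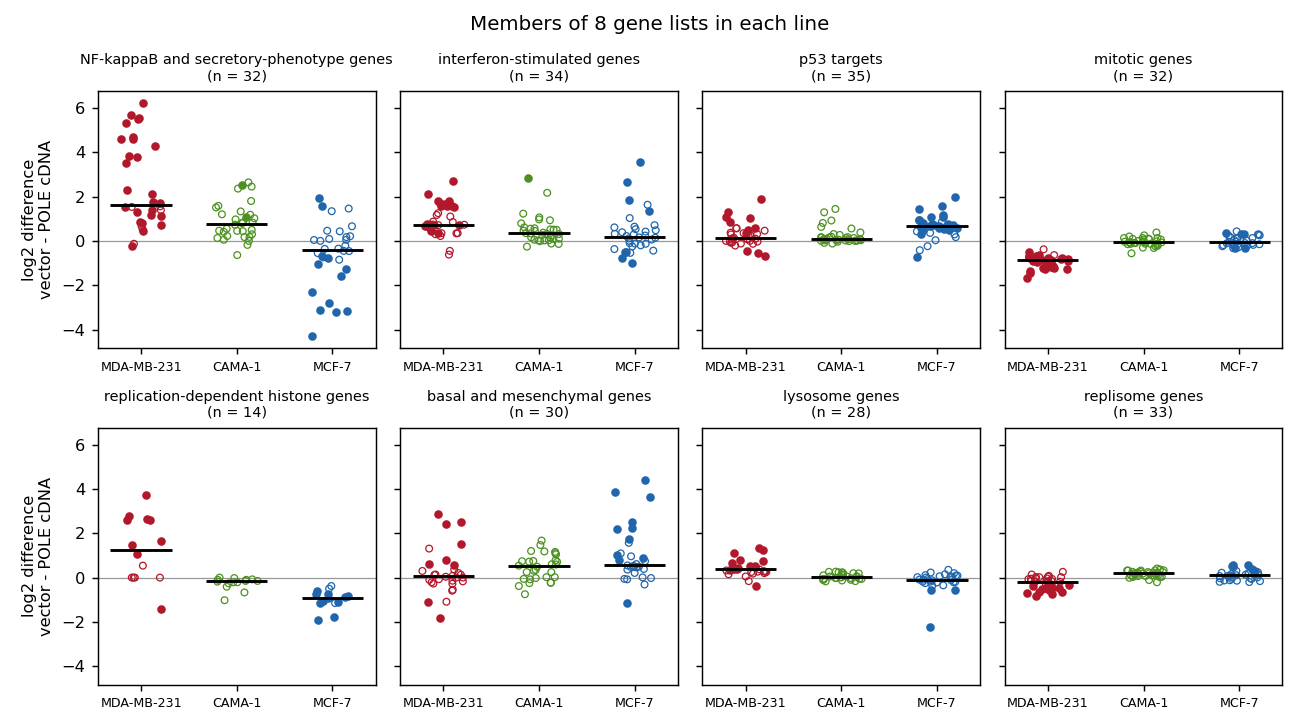
Members of 8 gene lists in each line, as the log2 difference of vector minus POLE cDNA. Filled points are genes with a limma adjusted p under 0.05, open points the others, and bars the median, and in MDA-MB-231 the NF-kappaB list has a median of 1.64 and the mitotic list of -0.87.

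Across 16705 genes without POLE, the correlation of log2 differences was 0.121 between MDA-MB-231 and CAMA-1 (Spearman 0.131), 0.046 between CAMA-1 and MCF-7 (0.047) and -0.039 between MDA-MB-231 and MCF-7 (-0.037). Genes are not independent replicates. MDA-MB-231 and MCF-7 shared 1025 called genes, of which 457 had the same direction. Higher in both were 309 genes, where independence gives 243.9, and lower in both 148 (138.6). In opposite directions, 358 were higher in MDA-MB-231 and lower in MCF-7 (210.3) and 210 the reverse (160.7). The lines share 1 estimate of each gene's spread, which may by itself raise overlaps in any direction above independence, also those with CAMA-1 that follow. Of the 28 genes other than POLE called in CAMA-1, 9 were higher (3.8) and 1 lower (0.1) in both CAMA-1 and MDA-MB-231, and 0 were opposite (2.5 and 0.1). In MCF-7 6 of the 28 were higher too (2.8) and 8 were lower (2.4).

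**Figure D3:**
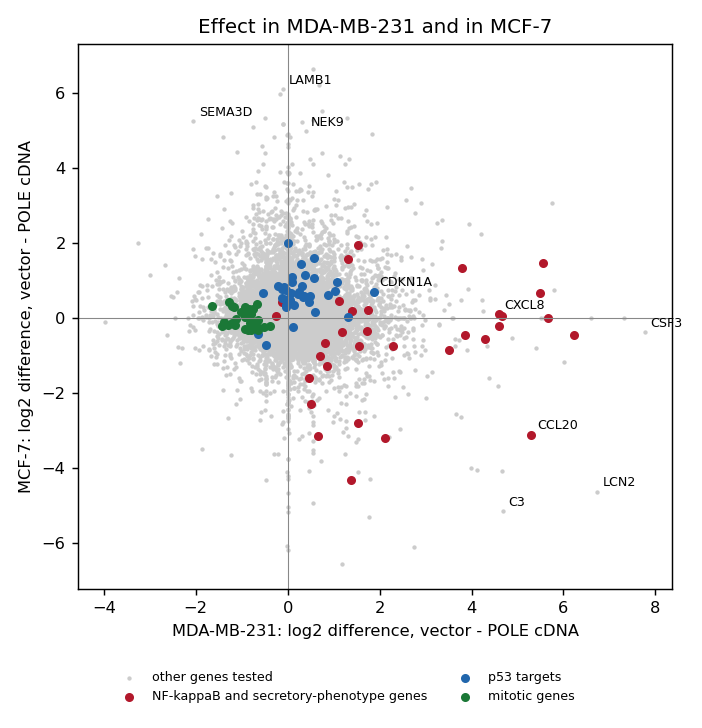
The log2 difference of vector minus POLE cDNA in MDA-MB-231 and in MCF-7 for each tested gene other than POLE, with 3 lists in color. The NF-kappaB genes lie mostly to the right of 0 in MDA-MB-231 (25 of 32 rose), the p53 targets above 0 in MCF-7 (24 of 35 rose), and the mitotic genes to the left of 0 (29 of 32 fell in MDA-MB-231).

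The mean over the 3 lines can be carried by 1 or 2 of them, and the genes named here had the same sign in each. The chemokine CXCL1 was 7.13-fold higher (log2 2.83 ± 0.37, SE, 2 libraries per arm in each line, limma adjusted p = 0.000776) and the TNF family ligand TNFSF15 5.93-fold (2.57 ± 0.23). COL17A1, a collagen of hemidesmosomes, was 4.49-fold higher (2.17 ± 0.13, limma adjusted p = 7.91e-06) and the small heat shock protein HSPB8 4.3-fold. CXCL8 (2.38), DIO2 (2.31), the protease inhibitor SLPI (2.25), NDRG2 (2.24), CXCL3 (2.24) and SCIN (2.11) also rose. After POLE the potassium channel KCNMA1 was 3.65-fold lower (-1.87 ± 0.22, limma adjusted p = 0.000458), followed by DCLK1 (-1.55), the adenylate kinase AK7 (-1.30), B3GALT5 (-1.04) and AC079613.1 (-1.03). DRAIC (-0.91), the glutathione transferase GSTA4 (-0.90), FAM102B (-0.81) and RNF152 (-0.81) fell less. CAMA-1 added little to several, with 0.06 for SCIN and -0.03 for DRAIC. Of these 20 genes 7 had 3 or fewer reads in an arm of some line (CXCL1, DIO2, SLPI, CXCL3, KCNMA1, AK7 and AC079613.1), so their fitted means rest in part on the pseudocount. CXCL1 stood at 8.4 and 10.92 normalized counts in the CAMA-1 vector libraries and at 14435.13 and 16169.51 in those of MDA-MB-231. CXCL8 stood at 78.97 and 78.64 and at 36257.44 and 37243.26. Both were among 14 genes chosen for at least 2000 normalized counts in the MDA-MB-231 vector arm, a much lower level in its cDNA arm and a CAMA-1 mean under 0.2% of the former. Their median level in the CAMA-1 vector arm was 0.0554% of that in the MDA-MB-231 vector arm, within the bound by which they were chosen.

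Of 35 p53 targets 21 rose and 1 fell on the mean over lines (28 and 2 adjusted over the list alone, median 0.34, camera adjusted p = 9.86e-10, adjusted p = 0.0934 with an estimated correlation). FAS stood at 1.15 and CDKN1A at 1.07. The rise was mostly that of MCF-7, with a list median of 0.657 and 24 of 35 members higher. The median was 0.136 in MDA-MB-231, where the list was not called, and 0.089 in CAMA-1, with 0 members called. Basal and mesenchymal genes rose in 15 of 30 cases and fell in 0 (16 and 0 adjusted over the list alone, median 0.44, camera adjusted p = 1.19e-07, adjusted p = 0.0934 with an estimated correlation), including NT5E (1.57). Their median was 0.059 in MDA-MB-231, where the list was not called, and 0.576 in MCF-7, and that of CAMA-1 (0.515) was 0 to 0.376 with low levels subtracted as carried-over RNA. NF-kappaB and secretory-phenotype genes rose in 21 of 32 cases and fell in 1 (23 and 1 adjusted over the list alone, median 0.80, camera adjusted p = 1.49e-08, adjusted p = 0.177 with an estimated correlation). In MCF-7 2 of these rose and 11 fell, a camera call lost without cDNA library 1 (adjusted p = 0.0577) and with an estimated correlation (adjusted p = 0.7). Interferon-stimulated genes rose in 13 of 34 cases and fell in 0 (15 and 0 adjusted over the list alone, median 0.49, camera adjusted p = 1.54e-07, adjusted p = 0.263 with an estimated correlation). Mitotic genes fell in 17 of 32 cases and rose in 0 (25 and 0 adjusted over the list alone, median -0.31, camera adjusted p = 4.03e-15, adjusted p = 0.177 with an estimated correlation). PLK1 stood at -0.62, and the fall was that of MDA-MB-231, with list medians of -0.874 there, -0.065 in CAMA-1 and -0.069 in MCF-7. Immediate early and AP-1 genes rose in 10 of 25 cases and fell in 2 (11 and 2 adjusted over the list alone, median 0.30, camera adjusted p = 0.000195, adjusted p = 0.0934 with an estimated correlation), among them FOS (1.58). Cell death genes rose in 8 of 21 cases and fell in 0 (8 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.0101, adjusted p = 0.0934 with an estimated correlation). BIK stood at 0.99. Lysosome genes rose in 8 of 28 cases and fell in 1 (8 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.0144, adjusted p = 0.685 with an estimated correlation). Cyclin, CDK and CDK inhibitor genes fell in 6 of 21 cases and rose in 2 (8 and 4 adjusted over the list alone, median -0.13, camera adjusted p = 0.0201, adjusted p = 0.346 with an estimated correlation). CKS2 stood at -0.54. In MDA-MB-231, CAMA-1 and MCF-7 the list medians were 0.735, 0.343 and 0.191 for interferon-stimulated genes and 0.242, 0.099 and 0.389 for AP-1 genes. In the same order they were 0.401, 0.001 and 0.114 for cell death genes and 0.372, 0.025 and -0.088 for lysosome genes. Those of cyclin, CDK and CDK inhibitor genes were -0.371, 0.061 and 0.008.

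Lists not called on the mean over lines follow with members higher and lower. They were E2F and G1/S genes (5 and 2 of 31, 6 and 3 adjusted over the list alone, median 0.06, camera adjusted p = 0.507), replisome genes (2 and 2 of 33, 1 and 1 adjusted over the list alone, median 0.04, camera adjusted p = 0.925) and DNA damage genes (0 and 2 of 33, 0 and 1 adjusted over the list alone, median 0.05, camera adjusted p = 0.6). Histone genes (5 and 2 of 14, 5 and 3 adjusted over the list alone, median 0.09, camera adjusted p = 0.507) joined opposite changes, with HIST1H1E at -1.45 and HIST2H2BE at 0.91. Unfolded protein genes (3 and 4 of 29, 3 and 4 adjusted over the list alone, median -0.06, camera adjusted p = 0.265) included SLC7A11 (-0.80). Others were cholesterol synthesis genes (2 and 1 of 23, 1 and 1 adjusted over the list alone, median -0.03, camera adjusted p = 0.692), hypoxia genes (5 and 1 of 25, 5 and 1 adjusted over the list alone, median 0.07, camera adjusted p = 0.275) and estrogen receptor genes (4 and 3 of 30, 5 and 3 adjusted over the list alone, median 0.03, camera adjusted p = 0.925). The last were cilium genes (1 and 2 of 23, 1 and 2 adjusted over the list alone, median -0.14, camera adjusted p = 0.0575), ribosomal genes (0 and 0 of 38, 0 and 0 adjusted over the list alone, median -0.004, camera adjusted p = 0.521) and fibroblast and leukocyte genes (0 and 0 of 6, 0 and 0 adjusted over the list alone, median 0.41, camera adjusted p = 0.527). For the replisome list the median and the test differed in sign.

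On the mean over lines limma called 2786 genes, 1813 higher and 973 lower, and 384 differed at least 2-fold. The higher share was 65.1%, and 54.2% under quantile normalization, and a mean of CAMA-1 and MCF-7 without MDA-MB-231 called 1718. The count fell to 1796 without vector library 2 of MDA-MB-231, and to 1856, 1771 and 1793 without cDNA library 1, cDNA library 2 and vector library 1 of CAMA-1. Without cDNA library 2 of MCF-7 camera no longer called the cyclin list (adjusted p = 0.0514) and the lysosome list (adjusted p = 0.0942). The lysosome list was also lost without vector library 1 of MCF-7 (camera adjusted p = 0.0511). Of 70 called named genes 52 were called without each library, though not AK7.

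The effect in MDA-MB-231 was then set against the mean of those in CAMA-1 and MCF-7, the test of whether the arms differed otherwise in the basal-like line. Among genes with a mean of at least 100 normalized counts over the 12 libraries, LCN2 differed most, by 9.06 ± 0.51 on the log2 scale (SE, 2 libraries per arm in each line, limma adjusted p = 3.54e-06). It rose by 6.73 in MDA-MB-231, stood at -0.03 in CAMA-1 and at -4.63 in MCF-7. CSF3 differed by 8.22, C3 by 6.47, MMP3, with 0 reads in both luminal lines, by 5.67 and NDRG2 by 5.34. SAA2, an acute-phase protein, had a fitted difference of 5.87 with 0 reads in the MCF-7 vector arm, so that value is no bound. On the other side stood genes that rose in MCF-7: SEMA3D (-4.94), the caveolin CAV1 (-3.62), LAMB1 (-3.32) and DLC1 (-3.29). SEMA5A (-3.38) and the sialyltransferase ST6GAL1 (-3.25 ± 0.80, limma adjusted p = 0.0166) had differences of similar size. Of these 12 genes CSF3, SAA2, MMP3, SEMA3D and ST6GAL1 had 3 or fewer reads in an arm of some line, so their fitted differences rest in part on the pseudocount. POLE itself differed by -1.37 (limma adjusted p = 9.83e-05), a larger fall in MDA-MB-231 than in the luminal mean.

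NF-kappaB and secretory-phenotype genes differed upward in 24 of 32 cases and downward in 1 (27 and 1 adjusted over the list alone, median 2.09, camera adjusted p = 1.52e-14, adjusted p = 0.125 with an estimated correlation). Mitotic genes differed downward in 25 of 32 cases and upward in 0 (30 and 0 adjusted over the list alone, median -0.92, camera adjusted p = 2.27e-18, adjusted p = 0.151 with an estimated correlation). KIF20A stood at -1.67 and the cyclin CCNB1 at -1.30. Histone genes differed upward in 8 of 14 cases and downward in 0 (9 and 0 adjusted over the list alone, median 1.75, camera adjusted p = 8.75e-10, adjusted p = 0.125 with an estimated correlation). HIST2H2BE stood at 4.23. Replisome genes differed downward in 15 of 33 cases and upward in 0 (16 and 0 adjusted over the list alone, median -0.35, camera adjusted p = 1.95e-08, adjusted p = 0.186 with an estimated correlation). TIMELESS stood at -0.91. E2F and G1/S genes differed downward in 11 of 31 cases and upward in 0 (14 and 0 adjusted over the list alone, median -0.30, camera adjusted p = 2.71e-05, adjusted p = 0.271 with an estimated correlation). UHRF1 stood at -0.91. DNA damage genes differed downward in 9 of 33 cases and upward in 0 (9 and 0 adjusted over the list alone, median -0.33, camera adjusted p = 5.79e-05, adjusted p = 0.353 with an estimated correlation). FANCD2 stood at -1.16. Cyclin, CDK and CDK inhibitor genes differed downward in 9 of 21 cases and upward in 0 (12 and 0 adjusted over the list alone, median -0.49, camera adjusted p = 2.56e-05, adjusted p = 0.132 with an estimated correlation), among them the cyclin CCND1 (-1.17).

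Lysosome genes differed upward in 13 of 28 cases and downward in 0 (17 and 1 adjusted over the list alone, median 0.42, camera adjusted p = 4.16e-06, adjusted p = 0.283 with an estimated correlation). NEU1 stood at 1.49. Interferon-stimulated genes differed upward in 9 of 34 cases and downward in 0 (9 and 1 adjusted over the list alone, median 0.45, camera adjusted p = 0.000966, adjusted p = 0.353 with an estimated correlation), among them ISG20 (1.98). Hypoxia and glycolysis genes differed upward in 10 of 25 cases and downward in 2 (12 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.00241, adjusted p = 0.255 with an estimated correlation). ANGPTL4 stood at 4.80. Cell death genes differed upward in 6 of 21 cases and downward in 0 (6 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 0.00405, adjusted p = 0.125 with an estimated correlation). BIK stood at 2.16. Basal and mesenchymal genes differed downward in 8 of 30 cases and upward in 4 (9 and 4 adjusted over the list alone, median -0.46, camera adjusted p = 0.0144, adjusted p = 0.272 with an estimated correlation), and camera did not call them against CAMA-1 alone (adjusted p = 0.149). The p53 targets differed downward in 6 of 35 cases and upward in 2 (8 and 3 adjusted over the list alone, median -0.21, camera adjusted p = 0.0288, adjusted p = 0.353 with an estimated correlation). CDKN1A stood at 1.21. The sign of the list reversed against CAMA-1 alone (camera adjusted p = 0.81). Ribosomal genes differed downward in 2 of 38 cases and upward in 0 (0 and 0 adjusted over the list alone, median -0.12, camera adjusted p = 0.0102, adjusted p = 0.621 with an estimated correlation). Cilium genes differed downward in 4 of 23 cases and upward in 0 (4 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 0.0488, adjusted p = 0.559 with an estimated correlation), led by TCTN2 (-1.30).

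Lists not called for the difference between lines follow with members higher and lower. Immediate early and AP-1 genes (8 and 4 of 25, 9 and 5 adjusted over the list alone, median -0.08, camera adjusted p = 0.518) had a median opposite in sign to the test and included IER3 (3.32) and FOS (-2.01). Fibroblast and leukocyte genes (2 and 0 of 6, 3 and 0 adjusted over the list alone, median 1.09, camera adjusted p = 0.0817) included CD14 (2.60). The others were unfolded protein genes (7 and 4 of 29, 8 and 4 adjusted over the list alone, median 0.20, camera adjusted p = 0.23), cholesterol synthesis genes (2 and 2 of 23, 1 and 2 adjusted over the list alone, median -0.11, camera adjusted p = 0.436) and estrogen receptor and luminal genes (8 and 3 of 30, 9 and 4 adjusted over the list alone, median 0.27, camera adjusted p = 0.252).

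For the difference between lines limma called 3330 genes, 1865 higher and 1465 lower, of which 1360 differed at least 2-fold. The higher genes made up 56% of calls, and 47.6% with TMM scaling. Against CAMA-1 alone 1435 genes were called, and leaving out cDNA library 2 or vector library 2 of MDA-MB-231 gave 1846 and 1750. Camera did not call the p53 list without MCF-7 cDNA library 2 (adjusted p = 0.0787) or vector library 1 (adjusted p = 0.0606). It lost the ribosomal list without MDA-MB-231 cDNA 1 (camera adjusted p = 0.114), MDA-MB-231 vector 1 (adjusted p = 0.316) or MCF-7 vector 1 (adjusted p = 0.062). The cilium list was lost without MDA-MB-231 cDNA 2 (camera adjusted p = 0.0951) or vector 1 (adjusted p = 0.0758), CAMA-1 cDNA 1 (adjusted p = 0.0553) or vector 2 (adjusted p = 0.0703), and MCF-7 cDNA 1 (adjusted p = 0.0859) or vector 2 (adjusted p = 0.237). Of 69 called named genes 56 were called without each library, though not ST6GAL1. The design holds 1 basal-like and 2 luminal lines, so the difference belongs to these lines and not to a subtype.

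**Figure D4:**
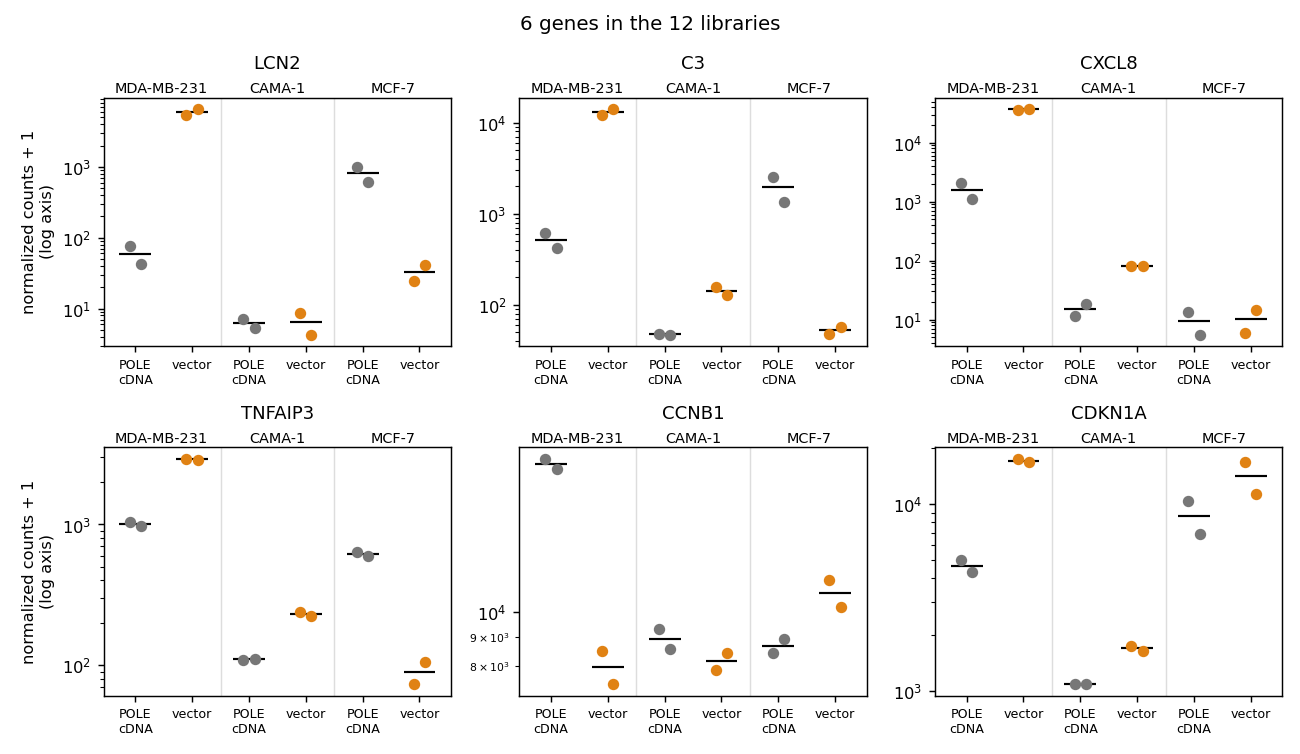
Normalized counts plus 1 of LCN2, C3, CXCL8, TNFAIP3, CCNB1 and CDKN1A in the 12 libraries on log axes. Points are libraries and bars the mean of 2, and LCN2 lies at 5452.6 and 6546.08 in the MDA-MB-231 vector libraries against 74.87 and 40.96 with the cDNA, and at 23.35 and 40.54 against 1009.05 and 616.07 in MCF-7.

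The POLE cDNA arms themselves differed between MDA-MB-231 and the mean of the luminal lines. Estrogen receptor and luminal genes were lower in MDA-MB-231 in 28 of 30 cases and higher in 2 (28 and 2 adjusted over the list alone, median -7.06, camera adjusted p = 7.55e-11, adjusted p = 0.0877 with an estimated correlation), including the pioneer factor FOXA1 (-10.07 ± 0.14, SE, 2 libraries per line) and GRHL2 (-9.88). Basal and mesenchymal genes were higher in 26 of 30 cases and lower in 2 (26 and 2 adjusted over the list alone, median 6.64, camera adjusted p = 8.17e-08, adjusted p = 0.0877 with an estimated correlation), including the receptor kinase AXL (11.90) and NT5E (10.71). NF-kappaB and secretory-phenotype genes already stood higher with the cDNA in 25 of 32 cases and lower in 4 (26 and 4 adjusted over the list alone, median 4.23, camera adjusted p = 1.07e-05, adjusted p = 0.398 with an estimated correlation). SERPINE1 stood at 10.41. Immediate early and AP-1 genes were higher in 18 of 25 cases and lower in 4 (18 and 4 adjusted over the list alone, median 1.70, camera adjusted p = 0.000467, adjusted p = 0.146 with an estimated correlation). FOSL1 stood at 9.03. On the low side FOXA1, GRHL2, AXL, NT5E and SERPINE1 had levels in the range of carried-over RNA or low transcription, so the sizes of these differences are not exact. Mitotic genes were higher in 30 of 32 cases and lower in 1 (30 and 1 adjusted over the list alone, median 1.07, camera adjusted p = 6.27e-06, adjusted p = 0.577 with an estimated correlation). BUB1 stood at 2.32. E2F and G1/S genes were higher in 26 of 31 cases and lower in 3 (26 and 3 adjusted over the list alone, median 0.69, camera adjusted p = 0.000295, adjusted p = 0.541 with an estimated correlation). CDC25A stood at 1.96. Replisome genes were higher in 18 of 33 cases and lower in 3 (18 and 3 adjusted over the list alone, median 0.42, camera adjusted p = 0.028, adjusted p = 0.671 with an estimated correlation). FEN1 stood at 1.36.

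Histone genes were lower with the cDNA in MDA-MB-231 than in the luminal mean in 12 of 14 cases and higher in 1 (12 and 1 adjusted over the list alone, median -3.01, camera adjusted p = 0.000295, adjusted p = 0.398 with an estimated correlation). Cholesterol synthesis genes were lower in 17 of 23 cases and higher in 4 (17 and 4 adjusted over the list alone, median -0.91, camera adjusted p = 0.0153, adjusted p = 0.655 with an estimated correlation). SQLE stood at -2.97. Interferon-stimulated genes were higher in 23 of 34 cases and lower in 9 (23 and 9 adjusted over the list alone, median 1.96, camera adjusted p = 0.0153, adjusted p = 0.671 with an estimated correlation), including IFIT3 (8.02). Ribosomal protein genes were higher in 24 of 38 cases and lower in 5 (24 and 5 adjusted over the list alone, median 0.37, camera adjusted p = 0.0136, adjusted p = 0.789 with an estimated correlation). RPL23 stood at 1.08. Not called, with members higher and lower, were p53 targets (14 and 17 of 35, 14 and 17 adjusted over the list alone, median -0.16, camera adjusted p = 0.521), DNA damage genes (19 and 5 of 33, 19 and 5 adjusted over the list alone, median 0.39, camera adjusted p = 0.168) and cyclin, CDK and CDK inhibitor genes (15 and 5 of 21, 15 and 5 adjusted over the list alone, median 0.53, camera adjusted p = 0.124). Nor were unfolded protein genes (15 and 7 of 29, 15 and 7 adjusted over the list alone, median 0.22, camera adjusted p = 0.493), hypoxia genes (12 and 7 of 25, 12 and 7 adjusted over the list alone, median 0.31, camera adjusted p = 0.263) and lysosome genes (8 and 15 of 28, 8 and 15 adjusted over the list alone, median -0.36, camera adjusted p = 0.427). The same held for cell death genes (9 and 7 of 21, 9 and 7 adjusted over the list alone, median 0.02, camera adjusted p = 0.918), cilium genes (7 and 4 of 23, 7 and 4 adjusted over the list alone, median -0.02, camera adjusted p = 0.77), whose test had the opposite sign to the median, and fibroblast and leukocyte genes (3 and 2 of 6, 3 and 2 adjusted over the list alone, median 1.82, camera adjusted p = 0.648). In all, limma called 13203 genes between these arms, 6466 higher and 6737 lower in MDA-MB-231.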

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

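Of the tests here, the exchange of arm labels and the sum of leukocyte and fibroblast genes were chosen before the data were examined, and all others after the results were seen.

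A difference between groups marked every result of this part: the difference between the arms in MDA-MB-231 was unlike the mean of those in CAMA-1 and MCF-7 for 3330 genes by limma. Over all tested genes that was 3330 of 16706. Among the named genes this held for 59 of 76 in MDA-MB-231, 22 of 50 in CAMA-1, 46 of 76 in MCF-7 and 39 of 77 on the mean over lines. Named genes were chosen largely by the size of differences that enter this test. Their shares were thus in part fixed by that choice and are no further evidence. Among genes with a mean of at least 100 normalized counts over the 12 libraries, the largest differences on one side were those of LCN2 (9.06), CSF3 (8.22), C3 (6.47), SAA2 (5.87), MMP3 (5.67) and NDRG2 (5.34). On the other were SEMA3D (-4.94), CAV1 (-3.62), SEMA5A (-3.38), LAMB1 (-3.32), DLC1 (-3.29) and ST6GAL1 (-3.25). By camera 15 lists differed as well. The adjusted p was 2.27e-18 for mitotic genes, 1.52e-14 for NF-kappaB genes, 8.75e-10 for histone genes, 1.95e-08 for replisome genes and 4.16e-06 for lysosome genes. It was 2.56e-05 for cyclin and CDK genes, 2.71e-05 for E2F genes, 5.79e-05 for DNA damage genes, 0.000966 for interferon-stimulated genes and 0.00241 for hypoxia genes. The adjusted p was 0.00405 for cell death genes, 0.0102 for ribosomal protein genes, 0.0144 for basal genes, 0.0288 for p53 targets and 0.0488 for cilium genes, and 0 lists were called with an estimated correlation.

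Arm labels exchanged within lines gave as many genes as the mean over lines in 2 of 100 relabellings (2786 called, at most 2884) and as many as the difference between lines in 3 of 100 (3330 called, at most 3748), the real labels included in both counts. The highest count with the arms of a line mixed was 2303 and 3174. The other relabellings at or above the real count exchanged whole lines, and so kept each difference and turned its sign.

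Of 32 NF-kappaB genes 25 rose and 1 fell in MDA-MB-231 without the cDNA, and 2 rose and 11 fell in MCF-7, with camera calls that were both lost with an estimated correlation (adjusted p = 0.117 and 0.7) and the second also without cDNA library 1 of MCF-7 (adjusted p = 0.0577). Exchanged labels in MCF-7 did not account for it, because POLE was lower with the vector there too (-3.96). For leukocyte or fibroblast RNA the highest sum of 8 such genes in an MDA-MB-231 vector library was 404.8 normalized counts, which met neither of the limits set beforehand and was mostly COL1A1. Values looked at after that sum, in 2 further versions, were divided. Without COL1A1 the sums were 29 and 32.6 with the cDNA and 36.7 and 26.9 with the vector. PTPRC, at low counts, fell from 9.36 and 8.38 to 2.75 and 2.24, while CXCL8 reached 36257.4 and 37243.3. But of the 6 tested genes of the fibroblast and leukocyte list 4 rose (CD14, CD68, HLA-DRA and COL1A1) and 0 fell, with a median of 0.95, though the list was not called. Such RNA is therefore left open in MDA-MB-231. It has no bearing on the fall in MCF-7, and a response of the cells to the POLE level stays untested.

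In MCF-7 26 genes were near silent in 1 arm and expressed in the other, with limits chosen after the data were seen (17 in MDA-MB-231 and 0 in CAMA-1). For the 18 silent with the cDNA, RNA of another line in the vector libraries would have to rise far more than it did: genes abundant in MDA-MB-231 rose by a median of 0.0355% of their level there, and those of CAMA-1 by 0.195%. RNA of another line in the cDNA libraries, for the 8 silent with the vector, was not tested. An effect that the lines share fits poorly too, since 1 of the 26 was called in the same direction in MDA-MB-231 and 5 in the opposite one. Cell populations that had diverged before the hairpin was added may explain it, but arm and population go together here and these data cannot separate that from an effect of POLE.

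In CAMA-1 camera called the basal and NF-kappaB lists higher without the cDNA, with 0 of 30 and 2 of 32 members called, and lost both with an estimated correlation (adjusted p = 0.188 and 0.174), while fry called 0 lists. Low levels of other genes abundant in MDA-MB-231 were higher as well. With these subtracted as traces of MDA-MB-231 RNA at cDNA levels, the basal median went from 0.515 to 0 and the NF-kappaB median from 0.767 to 0.765. That source could hardly lower the NF-kappaB list, whose genes are low in that arm, and with the same arm as source the medians were 0.376 and 0.405. Traces may therefore make up part of either list, but their source is not known, and low transcription of the same genes in CAMA-1 cells was not told apart from carried-over RNA.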

How the results depend on the processing

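All alternatives here were chosen before the data were examined, except the means over pairs of lines, the comparisons with a single luminal line and the minimum mean within a line. No named gene called in the main fit or in the alternative changed direction under any scaling, filter, pseudocount or test in which it was tested. The direction of genes called in neither was not compared. Named genes were counted once in each comparison that named them, also where they were called in neither fit. Of these entries, 408 kept their side of the threshold under TMM scaling (3 lost it), 392 under quantile normalization, 393 with edgeR and 392 with DESeq2. All 64 list calls held under TMM scaling and 47 with fry. With an estimated correlation 0 lists were called in each of the 6 comparisons, and with fry 0 in CAMA-1. For the values that moved, the cause was not tested unless stated.

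With a minimum fold of 2 the counts were 1231 in MDA-MB-231, 1212 in MCF-7, 384 on the mean over lines, 1360 for the difference between lines and 8175 between the cDNA arms, fewer by construction. The count of CAMA-1 (29) was 15 under quantile normalization, 50 with a pseudocount of 8, 14 without a filter, 47 with a minimum mean of 50, 45 without trend, 50 with edgeR, 137 with DESeq2 and 0 with its libraries alone. MCF-7 alone gave 105, and MDA-MB-231 alone 3439. The mean of CAMA-1 and MCF-7 gave 1718, and the difference against CAMA-1 alone 1435. The correlation between MDA-MB-231 and CAMA-1 was 0.142 with a minimum mean of 50 and 0.146 with a pseudocount of 8.

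Leaving out 1 library gave 1866 to 5284 genes in MDA-MB-231, 6 to 89 in CAMA-1, 2063 to 4493 in MCF-7, 1771 to 4101 on the mean over lines, 1750 to 4776 for the difference and 11982 to 13691 between the cDNA arms. The correlation ranged from 0.086 to 0.124 between MDA-MB-231 and CAMA-1, from -0.078 to 0.003 between MDA-MB-231 and MCF-7 and from -0.001 to 0.087 between CAMA-1 and MCF-7. The p53 list reversed against CAMA-1 alone (camera adjusted p = 0.81). On the mean of CAMA-1 and MCF-7 reversed NASP (0.003), MCM5 (0.008), KIF20A (0.011), WEE1 (0.069), HIST2H2BE (-0.499), HIST1H2BC (-0.233), ANGPTL4 (-0.475), NEU1 (-0.144) and BCL2A1 (-0.041), and on that of MDA-MB-231 and CAMA-1 CTSZ (0.251). A replicate block gave 4869, 35, 4186, 3591, 4277 and 13598 genes in the order of the comparisons, but same-number libraries did not pair (correlations -0.031, 0.065 and 0.256). Genes near 0 reads in an arm are limited by depth.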

Other observations

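Families of genes with a common name stem were grouped after the lists had been seen, 255 with at least 8 tested genes. In MDA-MB-231 without the cDNA, splicing factors of the SRSF family fell in 6 of 11 cases and rose in 0 (median -0.41), and nuclear pore genes of the NUP family fell in 9 of 22 and rose in 0 (-0.28). RAB genes, of vesicle transport, rose in 19 of 65 cases and fell in 0 (0.22). In MCF-7 keratin genes rose in 13 of 30 cases and fell in 0 (0.86). Mitochondrial ribosomal genes (MRPL) fell in 11 of 50, proteasome genes (PSMD) in 7 of 14 and chaperonin genes (CCT) in 5 of 12, and 0 of them rose. No family was called by camera with an estimated correlation.

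Of the tests that follow, the one on windows of neighbouring genes was chosen before the data were examined, and the others after the results were seen. Few genes changed in CAMA-1, and neither the spread between its libraries nor the number of reads accounted for it. The residual SD of CAMA-1 was 0.986 of that in MDA-MB-231, and the mean reads were 1.066 of those in MCF-7. The POLE difference between the arms was larger than in MCF-7 (by -2.18 on the log2 scale). It came mostly from the cDNA level, 168240 normalized counts in CAMA-1 and 45336.2 in MCF-7, against 2391 and 2910 with the vector. It therefore cannot show how far the hairpin lowered POLE, and a weaker knockdown in CAMA-1 stays untested. Mitotic genes in the cDNA arm stood 0.22 above MCF-7 by median, with 9 of 32 lower, and -0.91 from MDA-MB-231, with 29 of 32 lower. Their level does not measure how often cells divided, so slower division in CAMA-1 stays untested.

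A hypothesis was that chromosome segments differed between the arms of MCF-7. In windows of 50 neighbouring genes, 14.27% lay beyond the range of shuffled windows in MCF-7, against 3.33% in MDA-MB-231, 2.9% in CAMA-1 and 0.2% by chance. The longest run, from CGNL1 to SNRPA1, held 270 genes with a median of 0.30, of which 82 were called higher and 6 lower. Shifted windows of either direction held 23% of placed genes, and 24.6% of the MCF-7 calls with a position lay in the direction of such a window. Windows and runs were chosen by these same differences, so calls in their direction were in part fixed by that choice and are no further evidence. A share of shifted windows above that of shuffled ones is what segments gained or lost would give. Regional regulation could give it too, and no DNA was measured. Segments did not account for the near-silent genes, whose neighbours had a median shift of 0.098, with 7 of 26 above 0.3.

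Genes abundant in one line and near silent in another had low levels there for each pair of lines, within the bound by which they were chosen, and carried-over RNA was not told apart from low transcription. Those of CAMA-1 stood at 0.0633% and 0.0615% of their level in the MDA-MB-231 cDNA libraries and at 0.0846% and 0.0817% in the vector libraries, and those of MCF-7 at 0.0644%, 0.0401%, 0.0967% and 0.0938%. In every pair most such genes were higher in the vector arm, from 70.9% to 87.5% of them. Their rise correlated with the level in the source line (Spearman 0.236 to 0.633). The bound on their level grows with that source level, so this does not tell the explanations apart.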
